A study of Homo sapiens with 4 samples.

How the data were processed

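Total RNA from HCT116 cells, an established human colon carcinoma line, was measured by RNA sequencing in 4 libraries: 2 from untreated cells and 2 from cells given 100 ng/ml TRAIL for 2 h. TRAIL is a secreted ligand of the TNF family that binds death receptors. Per the labels' protocols, RNA was isolated with TRIzol, depleted of ribosomal RNA with Ribo-Zero, and made into libraries with an NEBNext Ultra RNA kit, which does not mark the strand. Reads from a gene and from a partner on the opposite strand therefore cannot be told apart. The labels number the libraries of each group as repeats 1 and 2 and do not say whether these came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

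The deposited table holds 31580 rows of gene names. Per the submitters' processing notes, the tools were TopHat2, HTSeq and DESeq2 and the genome build was GRCh38. Versions, annotation and settings were not given in the sources used here. The values that the authors deposited are gene read counts divided by 1 size factor per library, a normalized signal, which the file header and the values show. Dividing each column by its smallest value above 0 returned whole reads for 100% of values in each library, within 0.001 of a read. The recovered totals were 14612484 and 15091240 reads in the untreated libraries and 13105640 and 12872116 in the TRAIL libraries. The size factors were 0.978, 0.819, 1.114 and 1.117 in the same order. The table also holds the authors' own adjusted p-value per gene, deposited for 13212 genes. There were 0 other columns of values per sample.

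The deposited size factors were not those that the median of ratios gives over all genes of the table. They lay within 0.03 (log2) of the median of ratios over the small nuclear RNAs alone, in a comparison made here class by class. A median change near 0 in that class is therefore set by the scale. The numbers of genes above and below 0 depend on the scale too, and 5 other scalings were run.

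Gene names were matched to GENCODE release 29 on GRCh38. By name, 22239 rows matched, another 674 matched through older or newer symbols, 21 were ambiguous and 8620 did not match. A spreadsheet had turned 26 names into dates, and 22 of these rows were tested without a gene identity. RNA classes came from the annotation and from name patterns. Unmatched names of the clone type were kept as a class of their own. Structural noncoding RNAs were defined as small nuclear RNAs (snRNAs), small nucleolar RNAs (snoRNAs) with the scaRNAs of Cajal bodies, and the 7SK, 7SL, RNase P, RNase MRP, vault, Y and telomerase RNAs. Names such as those of snRNA and Y RNA copies can merge or share reads of near-identical loci, and their values are uncertain for that reason.

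The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1) of the deposited values. Genes with a mean of at least 10 over the 4 libraries were tested, 16037 in all. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Changes are TRAIL minus untreated on the log2(value + 1) scale, which understates the change of genes with low values. The variance prior had infinite degrees of freedom, so genes of the same level shared 1 variance and the standard error (SE) had a median of 0.381. A gene whose replicates differ far more than others of its level therefore gets a p-value that is too small, and the authors' deposited adjusted p is given for such genes. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 (two-sided), so no permutation test was used for single genes. Sets of genes were compared with all other tested genes by limma's camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, and tested for movement in 1 direction by fry. With 4 libraries the estimated correlation rests on few residuals. A set that is not called with it is not shown to be unchanged.

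These choices were made before the data were examined: the test, the filter, 34 gene lists, most of the alternatives and the rule for the genes named. The rule took, among genes past the threshold with a mean of at least 100 and no overlap between groups, the 10 protein-coding genes with the largest rise, the 10 with the largest fall, and the 5 noncoding RNAs of each direction. It added 27 preset genes, and up to 4 members of each list with the smallest p. The alternatives were the repeat number as a block, each library left out, pseudocounts of 0.5 and 5, no filter and a filter at a mean of 50, 5 scalings, limma without the trend, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered whole reads. A removal of the GC trend, alone and with the block, the structural class without snRNA copies, and edgeR with TMM factors were added after seeing the data.

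The test was tried on simulated counts for the comparison of TRAIL with untreated, with 200 changed genes among 16037 in each of 5 runs. It recovered 66.6% of the 4-fold changes and 7.4% of the 2-fold changes, with 4.8% false calls and 0 calls of the wrong sign. Genes were simulated as independent and without differences shared by libraries of the same number, so the share of false calls in the real data may differ. In a further simulation, 12662 protein-coding genes were set 1.5-fold lower, and 1% of them were recovered. Libraries of a group were not copies of each other: the chi-square of their reads per degree of freedom was 49 for the untreated pair and 34.6 for the TRAIL pair.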

Results

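The study set RNA of apoptotic HCT116 cells against that of untreated cells, and asked how far messenger RNAs and noncoding RNAs are lost early after a death signal. HCT116 is a human colon carcinoma line, and TRAIL triggers the extrinsic apoptosis pathway through its death receptors. There were 2 untreated libraries and 2 libraries from cells treated with 100 ng/ml TRAIL for 2 h. The reads assigned to genes numbered 14612484 and 15091240 in the untreated libraries and 13105640 and 12872116 in the TRAIL libraries. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. The mitochondrial 16S ribosomal RNA MT-RNR2 took 15.2% of the normalized signal in each untreated library, and 19.3% and 22.5% in the TRAIL libraries. Protein-coding genes took 69.8% and 70.8% in the untreated libraries against 61.1% and 57.3% after TRAIL. Values below are the authors' normalized counts as mean ± SD (n = 2 per group) unless stated.

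Chemokine genes had large rises after TRAIL. CXCL1 went from 15.2 ± 11.3 to 1925 ± 294 normalized counts, a log2 change of 7.09 (SE 0.39, limma adjusted p = 5.99e-71). CXCL8, which encodes interleukin 8, went from 44.2 ± 39.4 to 3710 ± 893, a log2 change of 6.68 (SE 0.38, limma adjusted p = 7.29e-66). Their neighbours CXCL3 and CXCL2 had log2 changes of 5.67 and 5.61. All 4 lie on chromosome 4 (GRCh38), with CXCL8 at 73740506 to 73743716, CXCL1 at 73869393 to 73871242, CXCL3 at 74036589 to 74038807 and CXCL2 at 74097035 to 74099293. Among genes with a mean of at least 100 and no overlap between groups, the other protein-coding genes among the 10 largest rises were TNFAIP3 (log2 change 4.52), which encodes the NF-kB feedback inhibitor A20, FOSB (4.43), NFKBIZ (4.16), FAM166A (4.15), FOS (3.93) and NUAK2 (3.88). Of these 10, all but FAM166A were past the threshold in each of the 4 fits that left out a library. FAM166A had an adjusted p of 0.0527 without untreated 1.

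Many more genes were lower. On the deposited scale 3973 of 16037 tested genes fell (24.8%) and 567 rose (3.5%), by limma with Benjamini-Hochberg adjustment. Of the genes that fell, 3467 did so at least 2-fold and 20 at least 4-fold, whereas 190 of the genes that rose did so at least 4-fold. Among protein-coding genes with a mean of at least 100 and no overlap between groups, the largest fall was that of TM9SF2, a membrane protein gene on chromosome 13 (99446311 to 99564006), from 3967 ± 928 to 962 ± 261 (log2 change -2.05, SE 0.38, limma adjusted p = 1.4e-05). ZMPSTE24, the protease that matures lamin A, went from 2296 ± 622 to 577 ± 125 (log2 change -1.98, SE 0.38, limma adjusted p = 3.08e-05). The next in size were ZNF566 (-1.95), ZDHHC20 (-1.94), DPY19L1 (-1.93), TMTC3 (-1.93), HLTF (-1.93), SDHD (-1.90), RBM27 (-1.89) and TSPAN6 (-1.89). The authors' deposited adjusted p was under 0.05 for 4357 genes, of which 4046 were lower in TRAIL and 311 higher, and 3592 of the former were among the falls found by limma.

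The balance of rises and falls depended on the scale. The median log2 change of all tested genes was -0.585 on the deposited scale and -0.081 with equal library totals, -0.08 with TMM factors, -0.112 with the median of ratios, -0.021 with the mitochondrial DNA-encoded mRNAs held level and -0.529 with the structural RNAs held level. The numbers that rose and fell were 146 and 1 with library totals, 217 and 2 with TMM, 196 and 2 with the median of ratios, 700 and 77 with the mitochondrial mRNAs, and 438 and 2018 with the structural RNAs. The share of rises among all calls was then 99.3%, 99.1%, 99%, 90.1% and 17.8%, against 12.5% on the deposited scale. At an unadjusted p under 0.05, limma with TMM gave 1811 genes higher and 1980 lower, and with library totals 1813 and 2073. With TMM, totals and the median of ratios the variance prior also dropped from infinite to 4.75, 4.3 and 4.66 degrees of freedom. How far this drop added to the loss of calls was not tested. The 2 genes that fell with TMM were HLTF and the mitochondrial tRNA MT-TP. Below, "rose" and "fell" refer to the deposited scale, and the median of a class or list is also given relative to the median of all tested genes.

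The counts also rested on each library. A fit without 1 library leaves the repeat numbers unbalanced between groups, so a difference between repeats enters its values. Without untreated 1, limma called 12 genes higher and 0 lower (490 and 5713 at an unadjusted p under 0.05), without untreated 2 47 and 0 (942 and 3241), without TRAIL 1 298 and 1665, and without TRAIL 2 71 and 80. Each fall named below was thus past the threshold with all 4 libraries but not without either untreated library. Of the rises named below, those of SNORD3B-2, SNORD12C, SNORD12B, VPS9D1-AS1, GAS5-AS1, LINC-PINT, SNHG12, BBC3, HIST1H1PS1 and RPS16 passed in none of these 4 fits.

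The median change of protein-coding RNAs lay below that of structural noncoding RNAs. Of 12662 protein-coding genes tested, 3807 fell and 323 rose, with a median log2 change of -0.687 (quartiles -1.04 and -0.27). Of 183 structural noncoding RNAs, 2 fell and 4 rose, with a median of -0.084 (quartiles -0.20 and 0.07). The 2 that fell were the Y RNA RNY1, a log2 change of -1.16, and the vault RNA VTRNA1-1 (-1.28). VTRNA1-1 had 150 and 75.7 normalized counts in the untreated libraries and 79.9 and 23.3 after TRAIL, so the groups overlapped, and the authors' deposited adjusted p was 0.136. The log2 change of VTRNA1-1 was -0.791 without untreated 1, -2.15 without TRAIL 1 and -0.414 without TRAIL 2. DESeq2 called 1 structural RNA lower and 3 higher. The medians differed by -0.603. This difference was -0.399 and -0.409 when TRAIL 1 and TRAIL 2 were compared with untreated 1, and -0.843 and -0.835 when they were compared with untreated 2. Untreated 2 and untreated 1 themselves differed by 0.515 in this measure, and TRAIL 2 and TRAIL 1 by -0.051. A scaling cannot move this difference, but the structural median was 0.39 to 0.48 with the 4 scalings other than the deposited and the structural. The structural RNAs stood above all other tested genes by camera with the preset correlation (adjusted p = 1.71e-06), and this was not past the threshold with an estimated correlation (adjusted p = 0.43). None of the 9 class calls among 12 classes held with an estimated correlation.

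The most abundant structural RNAs were among the preset genes. RPPH1, the RNA of RNase P, had 528550 ± 2349 normalized counts in untreated cells and 474316 ± 31140 after TRAIL. RN7SL1, the RNA of the signal recognition particle, had 189353 ± 37878 and 181045 ± 10554. RN7SK had 107186 ± 21562 and 93848 ± 9709. RMRP had 321877 ± 26691 and 291558 ± 905. Their log2 changes of -0.16, -0.05, -0.18 and -0.14 were not past the threshold, and with TMM factors they were 0.35, 0.46, 0.33 and 0.37. Without untreated 2, RN7SL1 was at 0.154, RN7SK at 0.026 and RMRP at -0.056. Without untreated 1 these 3 were at -0.257, -0.387 and -0.225, and RPPH1 was at -0.091 without TRAIL 2. Among box C/D snoRNAs, many of which guide ribosomal RNA methylation, 3 of 38 rose and the other 35 did not pass. These were SNORD3B-2 (log2 change 1.64), SNORD12C (1.28) and SNORD12B (1.07), and with adjustment over the list alone 2 rose. DESeq2 called 2 members of the list higher, limma called 0 with library totals, TMM or the median of ratios, and none of these 3 rises passed in any of the 4 fits without a library. No member of 53 box H/ACA snoRNAs, 17 scaRNAs or 23 spliceosomal and U7 snRNAs passed, by limma, edgeR or DESeq2, and adjusted over the list alone 0 of each passed as well. At an unadjusted p under 0.05, limma gave 0, 0 and 1 of these, all higher. The medians relative to all tested genes were 0.58 for box C/D, 0.49 for box H/ACA, 0.49 for scaRNAs and 0.51 for the snRNAs. Without untreated 1 they were 0.926 for box C/D snoRNAs and 0.757 for box H/ACA snoRNAs, and without untreated 2 they were 0.362 for box C/D snoRNAs, 0.217 for box H/ACA snoRNAs and 0.326 for the spliceosomal and U7 snRNAs. On the deposited scale the medians of these 4 lists lay just below 0, from -0.098 to -0.008, and they were above 0 with TMM factors. The preset camera adjusted p was 4.73e-05, 0.00422, 0.0929 and 0.00601, and the adjusted p with an estimated correlation was 0.906 for each. Without untreated 2 the preset camera adjusted p was 0.44 for box H/ACA snoRNAs and 0.253 for snRNAs, without TRAIL 1 it was 0.0734 for box H/ACA snoRNAs, and without untreated 1 it was 0.0478 for scaRNAs.

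**Figure D1:**
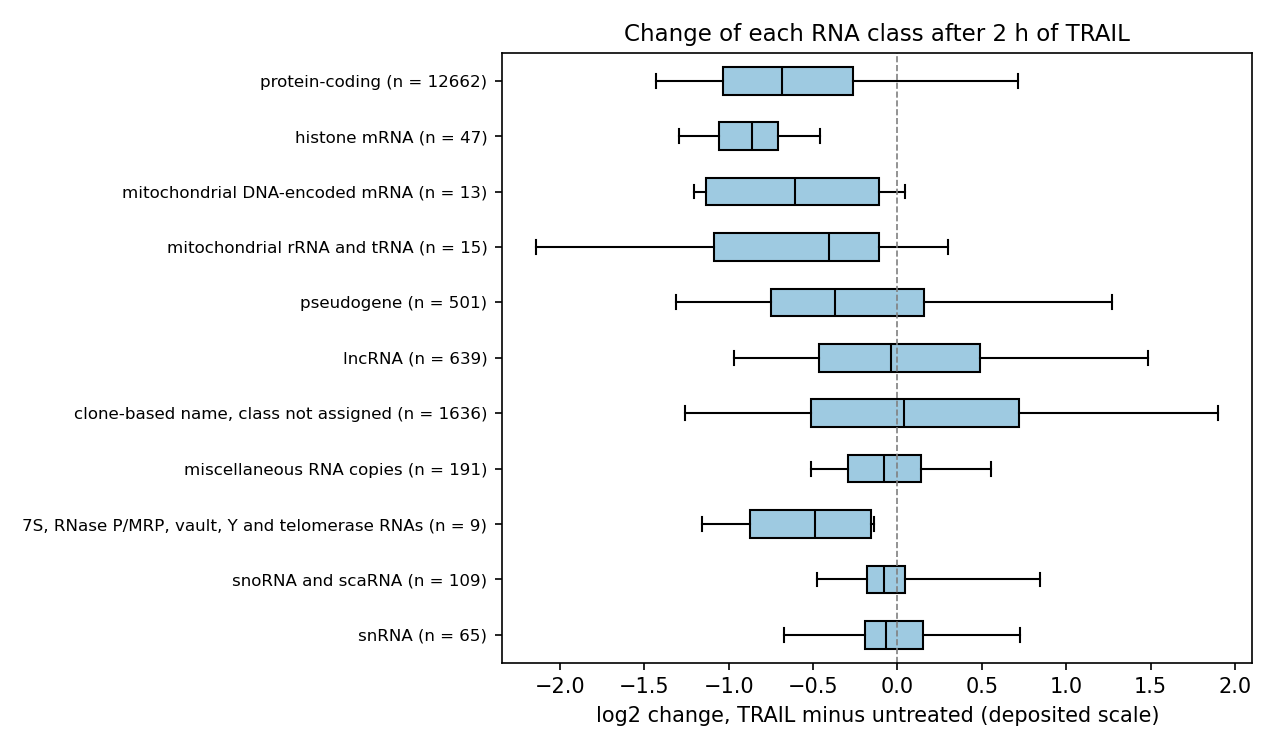
Box plots of the log2 change (TRAIL minus untreated, deposited scale, horizontal axis) of tested genes in each RNA class, with the median as a line, quartiles as the box, and the 5th to 95th percentile as whiskers. The median lies at -0.687 for protein-coding genes, at -0.067 for snRNAs and at -0.083 for snoRNAs and scaRNAs.

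Long noncoding RNAs both rose and fell. Of 639 lncRNAs, 45 rose and 18 fell by limma, against 13 and 11 by DESeq2, and 10 and 0 by limma with TMM factors. Their median of -0.04 was 0.55 relative to the median of all tested genes and turned positive in each of the other 5 scalings (camera adjusted p = 3.88e-11, and adjusted p = 0.452 with an estimated correlation). Compared with the untreated mean, the lncRNA median was -0.176 in TRAIL 1 and 0.16 in TRAIL 2. NEAT1, the scaffold of nuclear paraspeckles on chromosome 11 (65422774 to 65445540), went from 1089 ± 555 to 10871 ± 5072 (log2 change 3.33, SE 0.38, limma adjusted p = 1.68e-15). The nearby MALAT1, also nuclear, had 30226 ± 16703 and 31892 ± 9781 and was not past the threshold (log2 change 0.16, limma adjusted p = 0.779), and MALAT1 was at -0.433 without untreated 1, 0.758 without untreated 2, 0.48 without TRAIL 1 and -0.156 without TRAIL 2. Among the noncoding RNAs with a mean of at least 100 and no overlap between groups, the other large rises were LINC00243 (2.98), VPS9D1-AS1 (1.53), GAS5-AS1 (1.30) and SNORD12C. GAS5-AS1 and VPS9D1-AS1 are named as antisense to other genes, and the libraries cannot separate their reads from those of the opposite strand. By the same limits the largest falls were in MT-TP (-2.54), MT-TY (-1.72), OIP5-AS1 (-1.48), PKI55 (-1.37) and FGD5-AS1 (-1.22). NEAT1 was past the threshold in 3 of the 4 fits with a library left out and had an adjusted p of 0.0527 without untreated 1.

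A list of lncRNAs labelled nuclear-retained was fixed beforehand, and the location of its members was not measured here. Of its 13 members tested, 4 rose and 1 fell, and the counts were the same when adjusted over the list alone. DESeq2 gave 2 and 1. LINC-PINT (log2 change 1.04) and KCNQ1OT1 (0.96) were among those that rose, and OIP5-AS1 was the fall. KCNQ1OT1 was at 0.576 without untreated 1 and 0.566 without TRAIL 2. The median was 0.524, or 1.11 relative to all tested genes (camera adjusted p = 6.53e-05, and adjusted p = 0.906 with an estimated correlation). Of 24 host genes of snoRNAs, SNHG12 alone rose (977 ± 234 to 1948 ± 275), and adjusted over the list alone it did not. Their median was -0.035, which was positive in the other 5 scalings (camera adjusted p = 0.00537, and adjusted p = 0.906 with an estimated correlation). Without untreated 1 or TRAIL 2 the camera adjusted p of the host list was 0.051 and 0.0698. Of 504 lncRNAs with antisense or intergenic names, 30 rose and 14 fell (16 and 4 adjusted over the list alone, 10 and 8 by DESeq2 over all genes), with TSC22D1-AS1 (2.77), CA3-AS1 (3.57) and LINC00944 (2.63, and 1.671 without untreated 1) among the rises. Their median was 0.51 relative to all tested genes (camera adjusted p = 1.3e-09, and adjusted p = 0.906 with an estimated correlation), and 0.335 without TRAIL 2. Clone-named transcripts, of which 1636 were tested, rose in 163 cases and fell in 68 (54 and 32 by DESeq2), and stood above other genes by camera (adjusted p = 4.5e-17, and adjusted p = 0.43 with an estimated correlation). Compared with the untreated mean, their median was -0.156 in TRAIL 1 and 0.297 in TRAIL 2.

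Many targets of NF-kB rose. Of 43 tested, 22 rose and 1 fell, and adjusted over the list alone 25 rose and 1 fell. Beside the 4 chemokines and TNFAIP3, NFKBIA, which encodes the inhibitor IkB-alpha, went from 845 ± 95.3 to 8432 ± 2735 (log2 change 3.28). BIRC3, which encodes the ubiquitin ligase cIAP2, went from 127 ± 69.3 to 1645 ± 676 (log2 change 3.74). The single fall was in BIRC5, the survivin gene, which is also a G2/M gene. The list median was 1.462, or 2.05 relative to all tested genes, and was above 0 under every scaling. Its camera adjusted p was 5.49e-64 with the preset correlation and 0.906 with an estimated correlation, where the unadjusted p was 0.0436. With TMM factors 20 of the 43 rose.

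Immediate early genes, transcribed within minutes of many stimuli, rose in 24 of 48 cases and fell in 1 (25 and 1 adjusted over the list alone). FOS went from 65.25 ± 19.95 to 983 ± 14.9 and FOSB from 24.96 ± 16.49 to 509 ± 135. DESeq2 gave 14 and 1, and limma with TMM factors 8 and 0. The list median was 1.105, or 1.69 relative to all tested genes (camera adjusted p = 6.82e-37, and adjusted p = 0.906 with an estimated correlation), and 0.985 relative to all tested genes without untreated 1. Part of this list differed between the untreated libraries. JUN had 105 normalized counts in untreated 1 and 1353 in untreated 2, against 5060 and 5707 after TRAIL. ATF3 had 103 and 947 in the untreated libraries and 771 and 938 after TRAIL. EGR1 had 20.5 and 125 against 556 and 523. The log2 changes were 3.82, 1.44 and 3.38, and limma called all 3, while the adjusted p in the authors' deposited table was 0.138 for JUN, 0.697 for ATF3 and 0.0411 for EGR1. Without untreated 1, ATF3 had a log2 change of -0.16, JUN of 1.989 and EGR1 of 2.105, and without untreated 2 ATF3 had 3.029. MYC, also on the list, had 3505 ± 1709 and 3008 ± 947 and did not pass (log2 change -0.17, and 0.35 with TMM), and MYC was at -0.685 without untreated 1, 0.353 without untreated 2, 0.161 without TRAIL 1 and -0.493 without TRAIL 2.

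**Figure D2:**
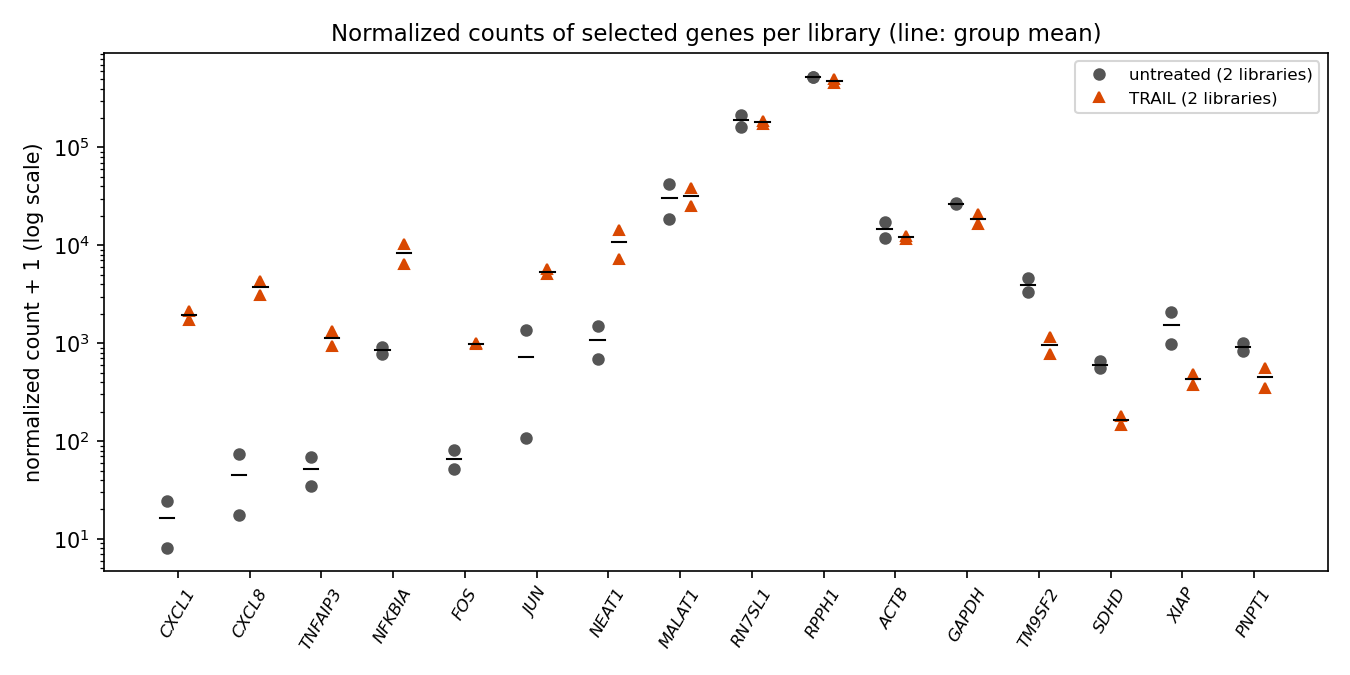
Normalized counts plus 1 (vertical axis, log scale) of 16 genes in each of the 2 untreated libraries (circles) and the 2 TRAIL libraries (triangles), with group means as lines. CXCL1 lies at 7.16 and 23.2 without TRAIL and at 2132 and 1717 with it, while RN7SL1 and RPPH1 overlap or nearly overlap between groups.

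Genes of the death receptor and caspase pathway were lower where they passed, with BIRC3 as the exception. Of 31 tested, 9 fell and 1 rose (15 and 1 adjusted over the list alone). XIAP, the caspase inhibitor, went from 1543 ± 794 to 428 ± 73.5 (log2 change -1.76), and BIRC5 from 5038 ± 543 to 1846 ± 769 (-1.51). The TRAIL receptor genes TNFRSF10A (1200 ± 276 and 632 ± 46.0, limma adjusted p = 0.0547) and TNFRSF10B (3908 ± 2560 and 2583 ± 795, adjusted p = 0.358) did not pass, nor did CASP8 (893 ± 292 and 464 ± 98.8, adjusted p = 0.0511) or CFLAR (752 ± 338 and 597 ± 94.1, adjusted p = 0.614). The authors' deposited adjusted p was 0.0283 for TNFRSF10A and 0.0416 for CASP8, and 0.292 for TNFRSF10B and 0.525 for CFLAR. Without untreated 2 TNFRSF10B was at 0.265 and CFLAR at 0.208, and without untreated 1 at -1.181 and -0.74. The list as a whole was not called by camera (adjusted p = 0.121). In the BCL2 family 5 of 19 fell, among them BNIP3L (-1.31), BCL2L13 (-1.20) and BNIP3 (-1.13), and BBC3, which encodes the death-promoting protein PUMA, rose (337 ± 89.3 to 681 ± 133, limma adjusted p = 0.0298). BBC3 had an adjusted p of 0.0857 to 0.334 without a library and of 0.0555 with TMM factors. Adjusted over the list alone 7 fell and 1 rose, and camera did not call it (adjusted p = 0.752). MCL1 had 3686 ± 1993 and 2469 ± 310 and did not pass (log2 change -0.47, and 0.04 with TMM), and MCL1 was at -1.051 without untreated 1 and 0.111 without untreated 2. Of 37 targets of p53, 10 fell and 3 rose (12 and 3 adjusted over the list alone, camera adjusted p = 0.582). RRM2B (-1.68), CPEB4 (-1.40), CCNG1 (-1.37) and FAS (-1.37) fell. CPEB4 was at -2.103 without untreated 1 and -0.696 without untreated 2, and FAS at -0.821 without TRAIL 2. The cell cycle inhibitor gene CDKN1A (5513 ± 1781 and 3083 ± 163) did not pass (limma adjusted p = 0.0945, deposited adjusted p = 0.0495).

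Many cell cycle genes fell. Of 34 G2/M genes, 23 fell and the other 11 did not pass (27 fell adjusted over the list alone). HMMR (log2 change -1.57), ECT2 (-1.55), TTK (-1.51) and BIRC5 (-1.51) had the smallest p. TTK was at -0.848 without TRAIL 2. The median was -1.147, or -0.56 relative to all tested genes (camera adjusted p = 0.000106, and adjusted p = 0.906 with an estimated correlation). Without untreated 1 the camera adjusted p was 0.0873. The median of the G2/M genes relative to all tested genes was then -0.322, and it was -0.229 without TRAIL 2 and -0.9 without TRAIL 1. Of 34 S phase genes, 16 fell and 18 did not pass (24 fell adjusted over the list alone). RRM1, a subunit of ribonucleotide reductase, went from 3156 ± 983 to 1013 ± 561 (log2 change -1.72, and -1.127 without TRAIL 2). The S phase median was -0.32 relative to all tested genes (camera adjusted p = 0.00422, and adjusted p = 0.906 with an estimated correlation). Without untreated 1 the S phase genes were at 0.025, without TRAIL 2 at -0.021, without untreated 2 at -0.722 and without TRAIL 1 at -0.711. Replication-dependent histone genes fell in 20 of 48 cases and rose in 2 (31 and 2 adjusted over the list alone). HIST1H4B went from 5082 ± 16.3 to 2117 ± 599 (-1.29). Of the 2 that rose, HIST1H1PS1 is annotated as a pseudogene and had 2.24 ± 0.28 and 21.5 ± 0.03 normalized counts. The histone median was -0.27 relative to all tested genes (camera adjusted p = 0.0148, and adjusted p = 0.906 with an estimated correlation), with camera adjusted p of 0.132 without untreated 1 and 0.105 without TRAIL 2. The median of the replication-dependent histone mRNAs relative to all tested genes was -0.127 and -0.088 in these 2 fits, and -0.456 without untreated 2 and -0.523 without TRAIL 1.

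A part of the nuclear genes for mitochondrial proteins fell. Of 77 mitochondrial ribosomal protein genes 31 fell (44 adjusted over the list alone) and of 79 respiratory chain genes 34 fell (48 adjusted over the list alone). No gene of either list was higher at an unadjusted p under 0.05 by limma, or past the threshold by edgeR or DESeq2. SDHD, a subunit of complex II, went from 604 ± 69.1 to 161 ± 24.4 (log2 change -1.90). ATP5A1, the alpha subunit of ATP synthase, went from 10641 ± 968 to 3539 ± 1378 (-1.64), and MRPS10 from 1113 ± 427 to 337 ± 49.4 (-1.67). The medians relative to all tested genes were -0.26 and -0.30 (camera adjusted p = 0.000106 and 0.000136, and adjusted p = 0.906 for both with an estimated correlation). Without untreated 1 these medians were -0.084 and -0.095, and without TRAIL 2 -0.11 and -0.14, with a camera adjusted p of 0.0545 for the respiratory chain without untreated 1. They were -0.467 and -0.564 without untreated 2, and -0.486 and -0.479 without TRAIL 1.

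RNAs made from mitochondrial DNA did not move together. Of 13 mRNAs, 4 fell, MT-ND3 (log2 change -1.49), MT-CO2 (-1.21), MT-CO1 (-1.17) and MT-ATP8 (-1.13), and 9 did not pass (4 fell adjusted over the list alone). MT-CO1 went from 28851 ± 7571 to 12970 ± 4269. MT-ND1 had 5290 ± 1672 and 3886 ± 770 and did not pass (limma adjusted p = 0.404). Of 15 ribosomal and transfer RNAs of the mitochondrion, 4 fell (4 adjusted over the list alone): MT-TP, MT-TC (-2.14, and -1.283 without TRAIL 2), MT-TY and MT-TV (-1.15). edgeR and DESeq2 each gave 4 lower and 1 higher. MT-RNR1 had 207631 ± 30003 and 401502 ± 18011 (limma adjusted p = 0.0628, deposited adjusted p = 0.0138). MT-RNR2 had 2535788 ± 372824 and 2430777 ± 233078 and did not pass. Camera called neither list (adjusted p = 0.582 and 0.519). The median of the mRNAs was below 0 under every scaling (-0.609 on the deposited scale, and -0.096 with TMM), and that of the ribosomal and transfer RNAs was -0.407 and turned positive in 4 of the other 5 scalings.

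Factors of mRNA decay fell in 33 of 69 cases and rose in 1 (40 and 1 adjusted over the list alone). This share, and those of the other lists that fell, were not compared with genes of matched GC content. SKIV2L2, the helicase that serves the nuclear exosome, went from 2561 ± 37.7 to 913 ± 213 (log2 change -1.51). CNOT7, a deadenylase, had a change of -1.47, the decapping enzyme DCP2 of -1.46 (-0.951 without untreated 2) and the exonuclease XRN2 of -1.44. PNPT1, the mitochondrial polynucleotide phosphorylase, went from 911 ± 125 to 453 ± 146 (-1.04, limma adjusted p = 0.0277), and DIS3L2, a cytoplasmic exonuclease, did not pass (526 ± 36.7 and 450 ± 95.8, adjusted p = 0.652). The list median was -0.34 relative to all tested genes (camera adjusted p = 0.0127, and adjusted p = 0.906 with an estimated correlation), and -0.19 without untreated 1 and -0.20 without TRAIL 2. Translation factors fell in 17 of 39 cases and rose in 1 (19 and 1 adjusted over the list alone). EIF3E went from 7087 ± 414 to 2220 ± 594 (-1.70), and the changes of EIF2S1, EIF3M and EIF4B were -1.42, -1.40 and -1.39. Their median was -0.23 relative to all tested genes (camera adjusted p = 0.0342, and adjusted p = 0.906 with an estimated correlation).

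Of 85 cytosolic ribosomal protein genes tested, 8 fell and 2 rose (1 and 2 adjusted over the list alone, 18 and 1 by DESeq2 over all genes), and their median of -0.576 was 0.009 relative to all tested genes (camera adjusted p = 0.582). RPL7L1, which entered the list by its name, fell (-1.28), and the rises were in RPS16 (206 ± 61.1 to 482 ± 57.6) and RPL3L, which had 2.05 ± 2.89 and 25.6 ± 0.59. Of 18 cytoskeletal housekeeping genes 3 fell, TUBB (-1.08, and -0.547 without TRAIL 2), MYL12B (-0.98) and MYL12A (-0.97), and 0 did when adjusted over the list alone (5 at an unadjusted p under 0.05 by limma, 2 by edgeR and 3 by DESeq2 over all genes). Camera gave that list an adjusted p of 0.519. ACTB had 14654 ± 3871 and 12123 ± 565, GAPDH 26601 ± 295 and 18519 ± 3071, and EEF1A1 15273 ± 6181 and 8888 ± 1252. None of these 3 passed, with log2 changes of -0.25, -0.53 and -0.73 on the deposited scale and of 0.26, -0.02 and -0.21 with TMM. GAPDH was at 0.04 with the mitochondrial mRNAs held level. Without untreated 1 ACTB was at -0.521 and EEF1A1 at -1.151, and without untreated 2 they were at 0.024 and -0.302.

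Of 24 genes of cholesterol synthesis 11 fell and 13 did not pass (12 fell adjusted over the list alone). MSMO1 went from 783 ± 4.05 to 247 ± 67.6 (log2 change -1.69), and SC5D, STARD4 and CYP51A1 had changes of -1.53, -1.51 and -1.49. STARD4 was at -2.363 without TRAIL 1 and -0.653 without TRAIL 2, with a deposited adjusted p of 0.0345. The median was -0.24 relative to all tested genes (camera adjusted p = 0.0276, and adjusted p = 0.906 with an estimated correlation). Without untreated 1 the median of the cholesterol list was 0.097, without TRAIL 2 it was 0.18, without untreated 2 -0.638 and without TRAIL 1 -0.707. Of 19 glycolysis genes 5 fell and 14 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.121), with PGK1 at -1.46 and LDHB at -1.34. The camera adjusted p of the glycolysis list was 0.0178 without untreated 2 and 0.00293 without TRAIL 1, with the preset correlation only, and with an estimated correlation and all libraries the adjusted p was 0.906. Of 21 heat shock genes 5 fell and 16 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.572), with HSP90AB1 going from 42623 ± 7993 to 16251 ± 6605. Of 386 zinc finger genes 108 fell and 7 rose (116 and 7 adjusted over the list alone). Their median of -0.73 lay near that of all protein-coding genes, -0.687, of which 30.1% fell. ZNF703 (2.54), ZNF296 (2.03) and ZNF469 (1.85, and 1.175 without untreated 1) were among the rises. The median of the zinc finger genes was -0.15 relative to all tested genes (camera adjusted p = 0.0276, and adjusted p = 0.906 with an estimated correlation), and the camera adjusted p was 0.286 without untreated 2 and 0.329 without TRAIL 1. The median of the C2H2 zinc finger genes was -0.009 and -0.04 in these 2 fits, -0.288 without untreated 1 and -0.25 without TRAIL 2.

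Several stress response genes differed between the repeats of a group. Of 30 genes of the integrated stress and unfolded protein responses, 11 fell and 2 rose (12 and 2 adjusted over the list alone), whereas edgeR gave 13 falls and 0 rises and DESeq2 8 and 0, and camera did not call the list (adjusted p = 0.582). Its median was -0.472 on the deposited scale and turned positive in 4 of the other 5 scalings. Relative to all tested genes it was 0.11, and it was -0.70 without untreated 1, 0.70 without untreated 2, 0.59 without TRAIL 1 and -0.60 without TRAIL 2, each past the threshold of camera with the preset correlation. With an estimated correlation and all libraries the adjusted p was 0.906. SLC7A11 had 2301 and 8233 normalized counts in the untreated libraries and 906 and 1831 after TRAIL. PPP1R15A had 300 and 3278, and 2772 and 4240 after TRAIL, and the adjusted p in the authors' deposited table was 0.0997 for SLC7A11 and 0.609 for PPP1R15A. Without untreated 1 SLC7A11 was at -2.675 and PPP1R15A at 0.065, and without untreated 2 they were at -0.836 and 3.512. SEL1L (-1.62, and -0.88 without untreated 2) and PSAT1 (-1.54, and -0.947 without untreated 2) fell by limma, with adjusted p of 0.00172 and 0.00215 in the authors' deposited table.

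**Figure D3:**
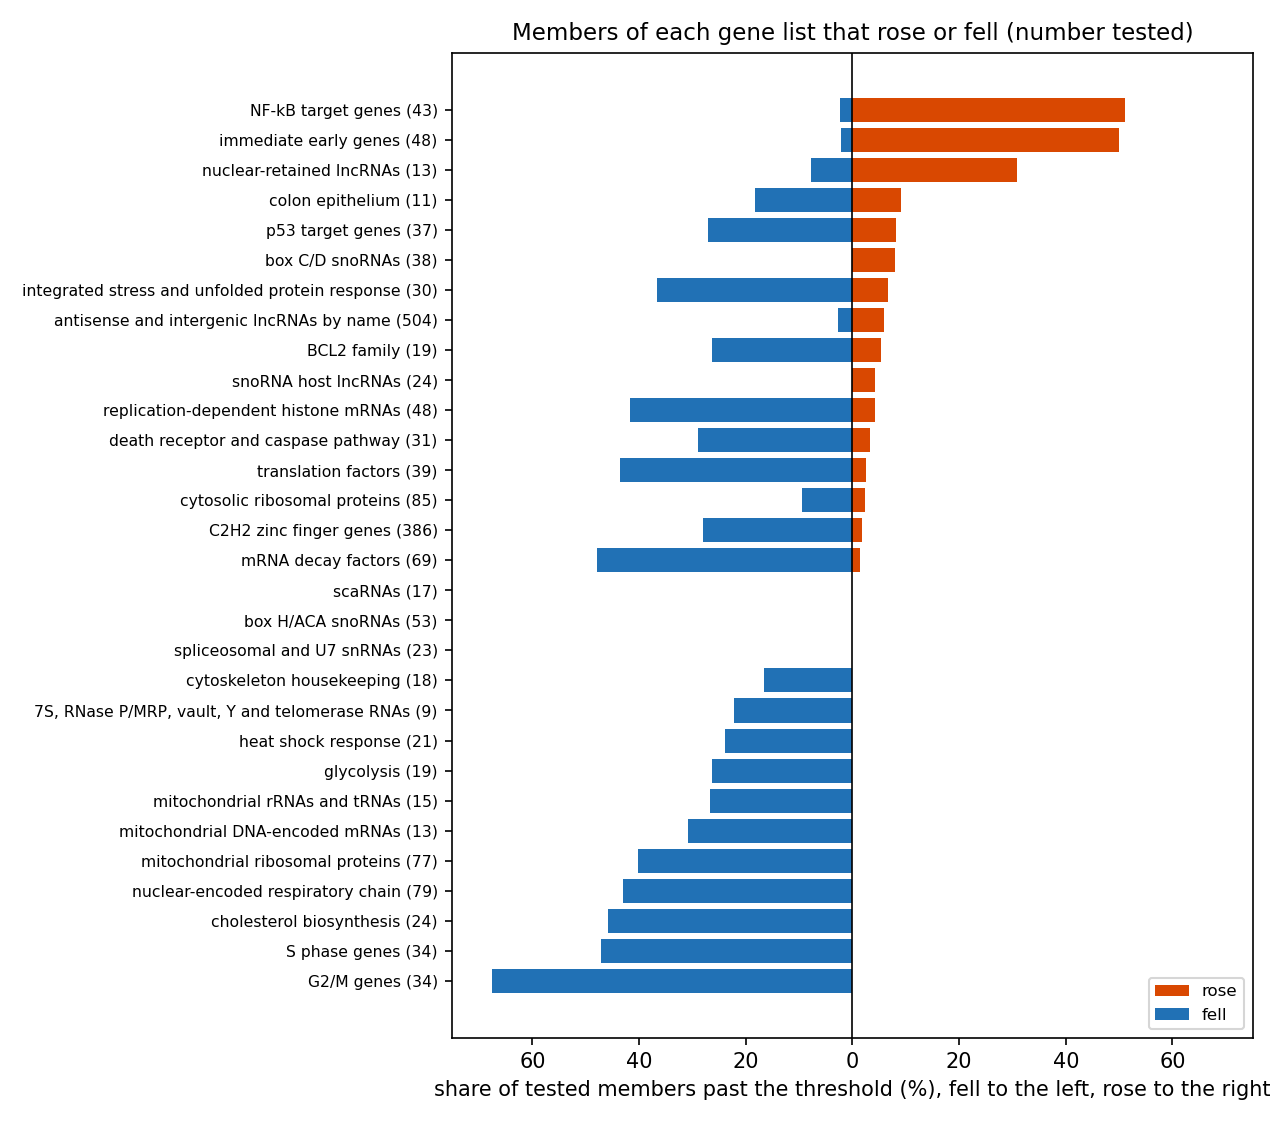
Share of tested members (horizontal axis, percent) of 30 gene lists that rose (to the right) or fell (to the left) after TRAIL by limma on the deposited scale, with the number tested in brackets. Of the NF-kB targets 22 of 43 rose, and of the G2/M genes 23 of 34 fell.

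Over the 30 lists with at least 3 tested members, camera with the preset correlation called 17, of which 8 were higher and 9 lower than other genes. These other genes include noncoding RNAs, and the median of protein-coding genes was -0.102 relative to all tested genes. For lists of protein-coding genes that difference enters the comparison. None of the 17 held with an estimated correlation, and fry called 0 lists (lowest adjusted p = 0.181). The estimated correlation was 0.442 for the NF-kB targets and 0.927 for the S phase genes. Such estimates from 4 libraries take in differences between repeats, so a list not called with them is not shown to be unchanged. Of 11 colon epithelium genes 2 fell, CDH1 (1021 ± 293 to 468 ± 21.7) and EPCAM (3489 ± 510 to 1686 ± 126), and ELF3, an epithelial transcription factor, rose (744 ± 120 to 2231 ± 670), and the counts were the same over the list alone (camera adjusted p = 0.582). Of the lists for other cell types, COL1A1 was the only gene that passed. This fibroblast collagen gene had 38.9 and 64.7 normalized counts in the untreated libraries and 126 and 218 after TRAIL (log2 change 1.70, limma adjusted p = 0.00124). The other fibroblast genes reached at most 54.7 (FBN1), and COL1A2 and DCN reached 1.80 and 1.20. The highest values were 18.8 (CSF1R) among leukocyte genes, 19.5 (HBG2) among erythroid genes and 91.6 (ESAM) among endothelial genes.

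The change of protein-coding genes followed their GC content. In the sixth of genes with the lowest GC content (30.2% to 40.1%) the median log2 change was -1.092, 61.6% fell and 0.6% rose. In the sixth with the highest (59.7% to 76%) the median was -0.161, 0.9% fell and 7.8% rose. The slope over 12633 protein-coding genes was 0.397 per 10 points of GC (SE 0.006 across genes, which are not independent replicates). Between single libraries the slope was 0.31 to 0.483 for the 4 pairs of a TRAIL and an untreated library, -0.145 between untreated 2 and untreated 1, and -0.027 between TRAIL 2 and TRAIL 1. Of the 10 falls named as largest among protein-coding genes, TM9SF2 had the highest GC content, 44.6%, and TMTC3 the lowest, 33.5%. Between 40.1% and 44% GC content 53.2% of protein-coding genes fell, and between 44% and 48.7% it was 38.4%. The decay factors named as falls had 35.7% (CNOT7) to 42.9% (XRN2). The gene lists were not compared with genes of matched GC content, so their falls are not shown to exceed those of such genes. With the GC trend removed, camera called 16 lists, against 17 in the main test.

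**Figure D4:**
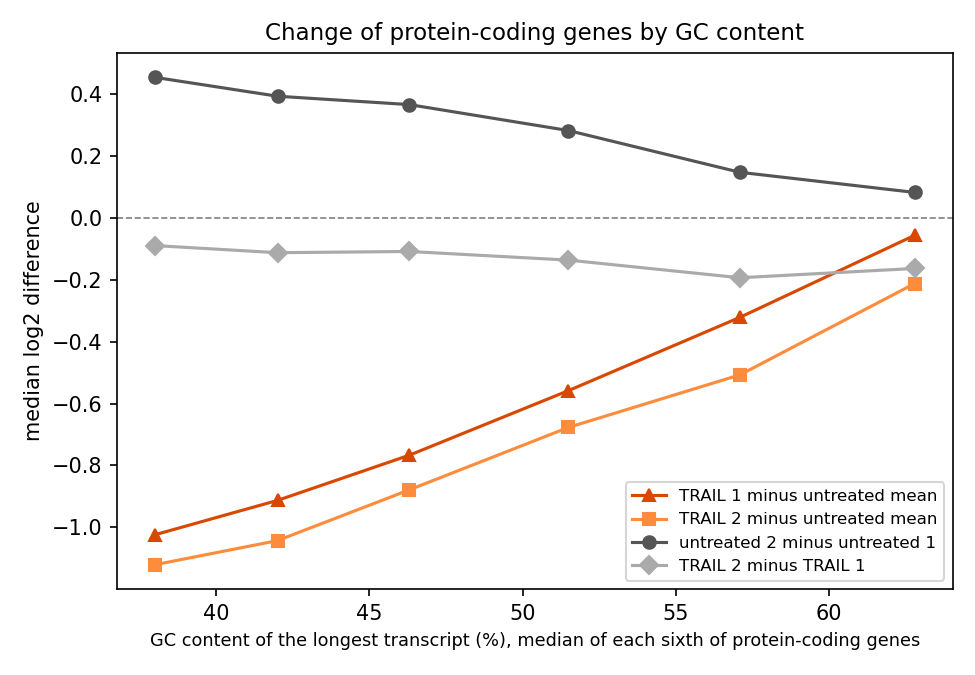
Median log2 difference (vertical axis) of protein-coding genes in 6 equal groups by the GC content of the longest transcript (horizontal axis, percent). The lines give TRAIL 1 and TRAIL 2 minus the untreated mean, which go from -1.02 and -1.12 at the lowest GC content to -0.06 and -0.21 at the highest, and the differences between libraries of a group.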

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

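The removal of the GC trend, the structural class without snRNA copies and edgeR with TMM factors were chosen only after the results were seen. The difference between protein-coding genes and structural RNAs cannot be moved by a scaling and kept its direction under every other alternative, from -0.85 to -0.431 in the fits without a library and -0.712 with the GC trend removed. Camera called 13 to 17 lists in the fits without a library. Without a library in turn, the numbers that rose, that fell, and of named genes past the threshold ranged from 12 to 298, from 0 to 1665 and from 9 to 94, where the lone library of a group was assumed to vary like the other group. The scalings gave 146 rises and 1 fall with library totals (21 named genes), 217 and 2 with TMM (26 named genes), 196 and 2 with the median of ratios (24 named genes), 2018 falls with the structural RNAs, and 77 falls with the mitochondrial mRNAs (55 named genes). edgeR with TMM factors gave 226 rises, 1 fall and 27 named genes. With no filter limma called 0 rises, 0 falls and 0 named genes (1600 and 5517 at an unadjusted p under 0.05), and with a mean of at least 50 there were 325 rises. limma without the trend gave 1229 falls and DESeq2 313 rises. Removal of the GC trend, in genes of known GC content, gave 267 rises and 3353 falls. Of these, 237 rises and 2225 falls were calls of the main test, which had 567 and 3973. The cause of these moves was not tested, except that a scaling moves every change by construction.

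The labels and the column names link samples of the 2 groups only by the repeat number and do not state a pairing. With the repeat number as a block 951 genes rose and 5390 fell. Among these were 566 of the 567 rises and 3932 of the 3973 falls of the main test. Camera then called 14 lists, without those of the histone mRNAs, decay factors and translation factors. The deviations of libraries with the same number correlated at 0.615 over tested genes (2 pairs). Libraries of the same number thus shared differences, which the main test, without a block, counted as spread. They also move the values of the fits without a library, where the repeat numbers are unbalanced between groups. ATF3 reversed to -0.156 without untreated 1, and was 3.029 without untreated 2. The integrated stress list lay between -0.698 (without untreated 1) and 0.698 (without untreated 2), with 0.586 without TRAIL 1, and the cholesterol list between -0.707 (without TRAIL 1) and 0.18 (without TRAIL 2), relative to all tested genes. Of 3360 values of named genes under alternatives, 2247 kept their direction and side of the threshold, 979 lost the threshold and 25 gained it, 108 changed sign without a call and 1 reversed. For 630 values of lists these counts were 530, 45, 19, 33 and 3. The direction of a list is there the one given by camera, which can differ from the sign of its median relative to all tested genes. The depth of 12872116 to 15091240 reads limits genes of low level most.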

Other observations

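The values in this paragraph and the next were picked after the results were seen, and some of the mitochondrial ones are also given above. MT-RNR1, the mitochondrial 12S ribosomal RNA, had a log2 change of 0.96 (limma adjusted p = 0.0628), while MT-RNR2 beside it had a log2 change of -0.06. Of the mitochondrial tRNAs, MT-TP, MT-TY and MT-TC, which fell, are encoded on the light strand, and MT-TV, which also fell, on the other strand. The light-strand mRNA MT-ND6 did not pass (2169 ± 504 and 1476 ± 237). Among the other rises, KMT2D, a histone methyltransferase gene, went from 367 ± 78.8 to 2178 ± 615, SRRM2 from 814 ± 136 to 3733 ± 505, and the fatty acid synthase gene FASN from 2023 ± 121 to 9158 ± 2697.

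Of genes with a mean of at least 200, 83 were at least 4-fold apart between the untreated libraries. Of these 82 were higher in untreated 2, and 81 lay on the same side in the TRAIL libraries. DDIT3 had 107 and 2091 normalized counts in the untreated libraries and 164 and 896 after TRAIL, and MT1E 804 and 12463 against 437 and 6370.

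Of the tests that follow, those of the authors' scaling and of neighbours matched on GC content were chosen only after the result was seen. Protein-coding genes of up to 1000 nt were lower than structural RNAs by a median log2 difference of -0.502 (95% interval with genes resampled -0.594 to -0.452). Structural RNAs such as RN7SK (328 nt) and SNORD12C (89 nt) are shorter, so the classes were not matched on length. Length is therefore not ruled out. Genes matched on level and GC content were lower by -0.537, and 95% of the random matchings gave -0.638 to -0.433. Level with GC content thus does not account for the whole difference. Both values rest on 4 libraries, and untreated 2 and untreated 1 differed by 0.515 in the same measure. With TMM factors 2 genes fell, but these factors centre the median change near 0 and the prior degrees of freedom dropped as well, so the count does not decide whether the authors' scaling caused the excess of falls. No external standard was analysed here that would set the scale.

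The fall of protein-coding genes with low GC content was tested against a GC bias of the libraries. Among structural RNAs the slope was -0.042 (SE 0.045) per 10 points of GC against 0.397 in protein-coding genes, which a bias acting on all RNAs alike would not give. The slope was 0.17 (SE 0.04) among 637 lncRNAs and 0.126 (SE 0.052) among 500 pseudogenes. The largest slope between libraries of a group was -0.145, and the 4 pairs of a TRAIL and an untreated library had larger slopes of 0.31 to 0.483. With 2 libraries per group this does not rule out a difference in GC response between libraries. A bias that acts on longer RNAs, coding or not, stays open.

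Genes of low level that rose were tested for reads from neighbours, with the matching on GC content added after the result. Of 184 such genes, 26.6% had an expressed gene ending within 20 kb upstream on the same strand, against a median of 19.6% in random draws matched on level and class, where 78 of 10000 draws had a share as large. Draws matched also on GC content were matched more coarsely on level, and 866 of 10000 of them had a share as large. Read-through therefore cannot be told apart from a link with GC content, and the coarser match on level may also have moved this count. An expressed gene on the other strand overlapped 29.3% of them, against 25% in random draws, and this cannot be told apart from chance. The nuclear-retained and the snoRNA host lncRNA lists differed by a median of 0.56 (permutation p over genes = 0.00739), a p that takes genes as independent although the estimated correlation within these lists was 0.263 and 0.488, so the difference stays open.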
